A study of Mus musculus with 6 samples.

How the data were processed

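Total RNA from jejunal mucosal scrapings of wild type and ISR2 mice was labelled with biotin by the Affymetrix whole-transcript protocol and hybridised to arrays, 3 per group, per the labels' protocols. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes; the log2 scale was read from their range (1.44 to 14.8). RMA corrects background, equalises the distributions of the arrays and summarises the probes of each probe set. Its version and any filters are not given in the sources used here. Equalising the distributions removes any change shared by most genes, so fold changes are relative to the bulk of the array. Background signal left after the correction can compress changes of dim genes. No detection call or background signal was used here.

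The table held 35556 rows. The annotation of the array gave 1 gene symbol to 21789 rows, several to 1621 and none to 12146. Of the rows with 1 symbol, 21698 matched the gene table of GRCm38.p6 by Entrez ID, and 0 symbols changed. That table was used only for names, and no coordinates are given because the annotation of the array names no build. Genes tested were rows with 1 symbol; of the 999 genes with several probe sets, the probe set with the highest mean over the 6 arrays was used, blind to group, which left 19938 genes. Of the 28 called genes with several probe sets, 0 had another called in the opposite direction and 13 had one that was not called. No intensity filter was applied. Gene list members without such a row, and 3 of the 8 genes named in advance, were not analysed here.

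Groups came from the sample titles. Each gene was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (no intensity trend, no robust option), ISR2 against wild type over all 6 arrays, without covariates. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, and are two-sided. A total of 28 gene lists were compared by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with a correlation estimated from the data and fry stand beside it. Fry's directional p asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The median log2 change of all genes was -0.06. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

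The lists, tests, main settings and the rule for named genes were set before the data were examined. The rule named 8 genes in advance, the 10 largest rises and 10 largest falls among called genes whose 3 ISR2 arrays all lay on 1 side of the 3 wild type arrays, and up to 4 members of each list with the smallest p. Predicted genes, pseudogenes and olfactory or vomeronasal receptors would have been skipped; 0 were skipped among rises and 0 among falls. Npc1, Ggps1 and Thrsp were named after their values were seen, as the only members of their lists to fall or not to pass.

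The steps were tested on simulated data for this comparison: 19938 genes with 200 changed, drawn with the spread of the real arrays. The test recovered 2% of genes changed by 0.5 on the log2 scale, 52% at 1, 94% at 2 and 98% at 4, and 8 of its 131 calls were false. Camera called 0 lists when none was changed, and found the 1 list that was shifted. The simulated genes vary independently, which those of real lists do not. Alternatives were eBayes with a trend or the robust option, array weights, median centring, quantile normalization, a filter on dim genes, all rows, the mean of a gene's probe sets, the replicate number as a block, other thresholds and each array left out in turn. A fit without wild type replicate 3 and ISR2 replicate 2, and array weights in the list test, were added after seeing the data.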

Results

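Gene expression was measured in mucosa scraped from the jejunum, the middle segment of the small intestine, of C57/BL mice aged 8 to 10 weeks on chow. The ISR2 mice are a transgenic line in which SREBP2 is overactive in the intestine. SREBP2, the product of Srebf2, is the transcription factor that switches on genes of cholesterol synthesis and uptake. The series holds 3 arrays of ISR2 mice and 3 arrays of their wild type littermates, and 19938 genes were tested. The values are on the log2 scale of the RMA method, and the medians of the 6 arrays over all rows lay between 6.04 and 6.19. Across genes, which are not independent replicates, Pearson's r was 0.978 to 0.991 between arrays of the same group and 0.970 to 0.982 between arrays of different groups. The number of arrays limits the precision. The labels do not say that each array came from a separate mouse, so the p-values measure the spread between these samples.

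The question was which genes differ in the jejunum when SREBP2 is overactive. Members of the cholesterol, sterol and fatty acid lists made up 7 of the 10 largest measured rises. Srebf2 itself was higher in ISR2 mucosa by 1.78 ± 0.16 on the log2 scale (SE, 3 arrays per group), a 3.43-fold rise, from 9.23 ± 0.24 to 11.01 ± 0.16 (mean ± SD, n = 3; adjusted p = 0.000298). The construct is not given in the sources used here, so the share of this signal that comes from the transgene is unknown. Srebf1, which encodes the related factor that drives fatty acid synthesis, rose 3.18-fold (log2 change 1.67 ± 0.15, SE; adjusted p = 0.000395). Insig1, which retains the SREBP proteins in the endoplasmic reticulum when sterols are plentiful, rose 10.4-fold (3.38 ± 0.11, SE; adjusted p = 8.2e-07).

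In all, 602 genes passed an adjusted p of 0.05 in limma, of which 356 rose and 246 fell. Of these, 223 rose and 104 fell at least 2-fold, and 31 rose and 4 fell at least 8-fold. Each of the 602 had all 3 ISR2 arrays on the same side of all 3 wild type arrays. Such separation held for 3943 genes, or 19.8% of those tested, where chance gives 10%. With each array centred on its median, 415 genes rose and 155 fell, so the balance of rises and falls depended on the scaling. The count was 345 without wild type replicate 1, 388 without wild type replicate 2 and 335 without ISR2 replicate 1, where 236 rose. The count of falls changed more than that of rises when 1 array was left out. Without wild type replicates 1, 2 and 3 in turn, 85, 128 and 170 genes fell. Without ISR2 replicates 1, 2 and 3 in turn, 99, 236 and 135 fell. Any fit with fewer arrays has less power, but the counts also depended on which array was left out. Without ISR2 replicate 2, 589 genes passed. With wild type replicate 3 left out as well, a fit chosen after seeing the data, 775 passed. The number of arrays alone therefore does not account for the drops. What sets the arrays apart was not tested. With all rows tested 106 fell, at an adjusted p of 0.10 386, and at an unadjusted p of 0.05 with a 1.5-fold change 404. With array weights 1268 genes passed, of which 630 rose and 638 fell.

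**Figure D1:**
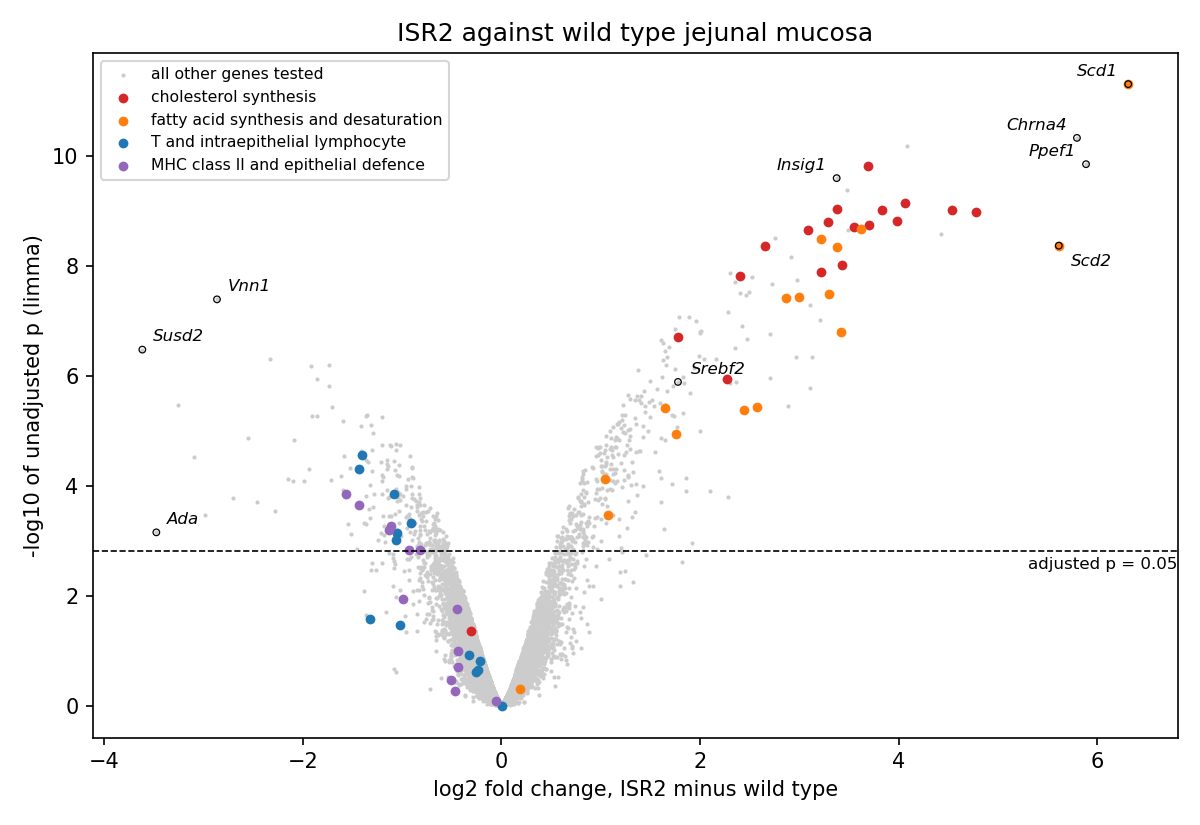
Each point is a gene, with its log2 fold change (ISR2 minus wild type, 3 arrays each) on the x axis and the negative log10 of its unadjusted limma p on the y axis. Coloured points are members of 4 gene lists, open rings mark the genes named, and the dashed line marks an adjusted p of 0.05; the cholesterol synthesis genes past the line all lie to the right of 0, and the T cell and MHC class II genes past it all lie to the left.

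Cholesterol synthesis genes rose almost as a whole. Of the 18 members measured, 17 rose and only Ggps1, which makes geranylgeranyl diphosphate on a side branch, did not pass (log2 change -0.31 ± 0.13, SE; adjusted p = 0.36). Adjusted over the list alone, 17 rose and Ggps1 fell. The median log2 change was 3.40, with the middle of the list between 2.76 and 3.80 (quartiles). Lss, which makes lanosterol from squalene epoxide, rose 27.5-fold (4.78 ± 0.19, SE), and Cyp51, the lanosterol demethylase, rose 23.3-fold (4.54 ± 0.18). Sqle, squalene epoxidase, rose 16.7-fold, and Mvd, mevalonate diphosphate decarboxylase, rose 15.9-fold. The sterol reductase gene Tm7sf2 rose 14.2-fold, the phosphomevalonate kinase gene Pmvk 12.9-fold and the mevalonate kinase gene Mvk 10.4-fold. The list passed the camera test with the preset correlation (adjusted p = 1.7e-63) and with an estimated correlation (adjusted p = 0.0195). The same 17-gene count was obtained without each array in turn.

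Genes of fatty acid synthesis and desaturation rose in 15 of 16 measured members, and also in 15 when adjusted over the list alone. The exception was Thrsp (0.19 ± 0.25, SE; adjusted p = 0.837), which was at -0.13 without ISR2 replicate 2. The median log2 change was 2.93. Scd1, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, had the largest measured rise of all named genes, 79.4-fold, from 7.30 ± 0.20 to 13.62 ± 0.03 (mean ± SD, n = 3). Its paralog Scd2 rose 48.9-fold, from 7.56 ± 0.60 to 13.18 ± 0.07. The coding sequences of this pair are close, and signal shared between their probes was not excluded. Acss2, which makes acetyl-CoA from acetate, rose 12.3-fold, and Me1, the cytosolic malic enzyme that supplies NADPH, rose 9.30-fold. The list passed camera with the preset correlation (adjusted p = 1.1e-47) and with an estimated correlation (adjusted p = 0.0327).

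In the list of sterol uptake and SREBP feedback, 7 of 13 measured members rose, 1 fell and 5 did not pass; adjusted over the list alone, 8 rose and 1 fell. The rises with the smallest p-values were those of Lpin1, a phosphatidate phosphatase of glycerolipid synthesis, with a log2 change of 4.08 ± 0.12 (SE), Insig1, Rdh11, a retinol dehydrogenase, at 7.52-fold and Stard4, a cholesterol transfer protein, at 3.04-fold. The member that fell was Npc1, which exports cholesterol from lysosomes, at a log2 change of -0.83 ± 0.13 (SE; adjusted p = 0.00709). Npc1l1, the transporter that takes up dietary cholesterol, differed by 0.17 ± 0.12 (SE; adjusted p = 0.639; 95% interval -0.10 to 0.44), and by 0.09 without wild type replicate 3 and ISR2 replicate 2. The list passed camera with the preset correlation (adjusted p = 2.6e-15) but not with an estimated correlation (adjusted p = 0.075). It passed fry upward (adjusted p = 0.00028).

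The list of LXR targets and sterol efflux held changes in both directions. Of the 10 measured members, 2 rose, 1 fell and 7 did not pass; adjusted over the list alone, 2 rose and 2 fell. Pltp, the phospholipid transfer protein gene, rose 6.74-fold, and Lpcat3, which remodels phospholipids, rose 1.76-fold. Abca1, the basolateral cholesterol exporter gene, fell by 1.03 on the log2 scale (SE 0.18; adjusted p = 0.0155). Its call was lost without wild type replicate 1, wild type replicate 2 or ISR2 replicate 3 (adjusted p up to 0.0665). Abcg5, a subunit of the apical sterol exporter, was -0.22 ± 0.13 (SE; adjusted p = 0.525; 95% interval -0.50 to 0.06), and -0.14 after median centring. The list's median was -0.14 and its mean 0.16, with opposite signs; the median was -0.19 to -0.08 without 1 array at a time, -0.07 after median centring, -0.08 with array weights and -0.04 without wild type replicate 3 and ISR2 replicate 2. Camera gave an adjusted p of 0.479, and fry gave 0.0271 in the upward direction (adjusted).

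Of the 10 largest measured rises, 3 were in none of these lists. Ppef1, a protein phosphatase with calcium-binding EF hands, rose 59.2-fold, from 4.03 ± 0.28 to 9.91 ± 0.26 (mean ± SD, n = 3). Chrna4, a nicotinic acetylcholine receptor subunit, rose 55.5-fold, from 5.90 ± 0.16 to 11.69 ± 0.25. Tmprss11f, a membrane serine protease, rose 21.4-fold from 4.08 ± 0.06 (log2 change 4.42 ± 0.19, SE). No background value shows that Ppef1, Chrna4 and Tmprss11f were detected in wild type. Their measured folds may therefore be lower bounds, and their place among the rises is not fixed. The adjusted p-values of Ppef1, Chrna4 and Tmprss11f were 5.8e-07, 4.3e-07 and 2.6e-06.

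The 10 largest falls ran from 12.3-fold to 5.02-fold. Susd2, a membrane protein with a sushi domain, fell by 3.62 on the log2 scale (SE 0.27). Ada, the adenosine deaminase gene, was 11.1-fold lower (-3.47 ± 0.69, SE; adjusted p = 0.0293), Slc28a2, a nucleoside transporter, 8.55-fold lower, and Nt5e, the ectonucleotidase that forms adenosine from AMP, 5.88-fold lower. Enpp3, another ectonucleotidase, was 5.52-fold lower. Slc34a2, a sodium-phosphate cotransporter, was 9.55-fold lower, Ly6m, a Ly6 family gene, 7.94-fold lower, and Vnn1, which releases pantothenate from pantetheine, 7.28-fold lower. Pck1, the phosphoenolpyruvate carboxykinase of gluconeogenesis, was 6.51-fold lower and Dnase1 5.02-fold lower. Some of these falls were uneven between ISR2 arrays: 6 of the 10 genes had an ISR2 SD above 0.6, while Vnn1 had 0.17 and Slc34a2 0.33. Ada stood at 8.42, 10.32 and 6.92 in ISR2 replicates 1, 2 and 3, and ISR2 replicate 2 was the highest of the ISR2 arrays in 9 of the 10 genes. Without wild type replicate 1 or ISR2 replicate 1, the calls of Ada, Ly6m, Pck1 and Enpp3 were lost, with adjusted p up to 0.147, 0.0835, 0.0619 and 0.0695; without wild type replicate 2, Ada and Ly6m were lost as well.

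**Figure D2:**
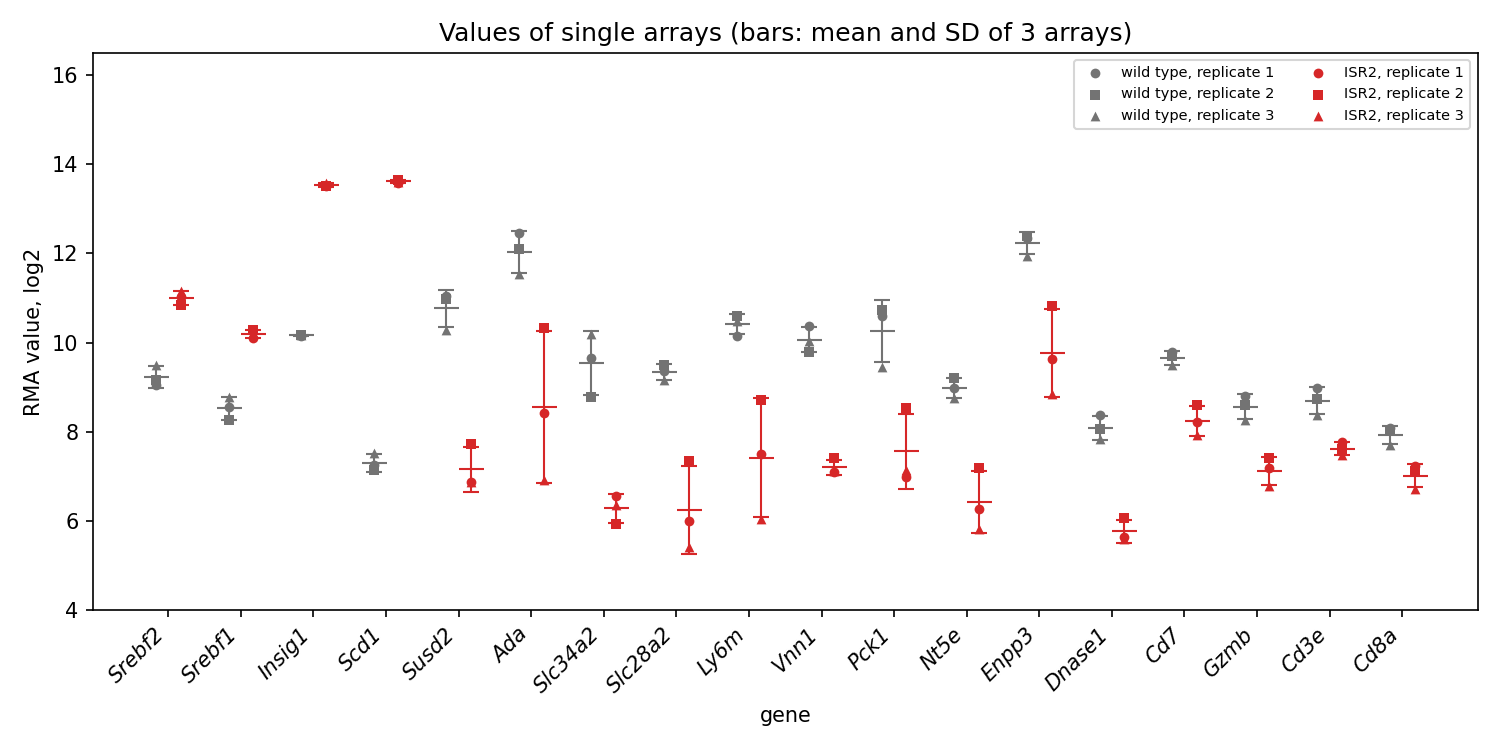
Log2 RMA values of single arrays are plotted for 18 genes, with wild type in grey and ISR2 in red, 3 arrays each, and bars giving the mean and SD. The ISR2 arrays of Srebf2, Srebf1, Insig1 and Scd1 lie above all wild type arrays, and those of the other 14 genes lie below, with Ada between 6.92 and 10.32 in ISR2.

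Genes of fat absorption, of digestion at the brush border and of proximal position fell in part. In the fat absorption list 3 of 16 measured members fell and 1 rose; adjusted over the list alone, 5 fell and 1 rose. Apoc3, an apolipoprotein of triglyceride-rich particles, fell by 1.72 on the log2 scale (SE 0.25), Slc27a4, a fatty acid transport protein, by 0.65 (SE 0.11) and Dgat2, which makes triglyceride, by 0.70 (SE 0.16). Scarb1, the HDL receptor gene, rose 2.13-fold. In the brush border list 3 of 13 fell and 5 adjusted over the list alone: Slc15a1, the peptide transporter, fell by 1.21 (SE 0.16), Treh, the enzyme that splits trehalose, by 0.82 (SE 0.13) and Alpi, the intestinal alkaline phosphatase, by 0.77 (SE 0.16). In the proximal list 2 of 7 fell and 4 adjusted over the list alone; Hsd17b6, a steroid dehydrogenase, fell by 1.13 (SE 0.18), and Ada is the other. Camera with the preset correlation gave adjusted p = 0.0209, 0.00676 and 0.000449 for the lists in this order, and none held with an estimated correlation (adjusted p = 0.647, 0.647 and 0.111). Fry gave adjusted p = 0.111, 0.0607 and 0.013 in the same order, so only the proximal list passed it. Without ISR2 replicate 1 the fat absorption and brush border lists no longer passed (adjusted p = 0.168 and 0.0639).

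Some calls in these lists were lost when 1 array was left out. In the fat absorption list 5 fell without ISR2 replicate 2 or with array weights, and 1 without any other single array or with all rows tested; in the brush border list 1 fell without wild type replicate 1 or ISR2 replicate 1. Slc27a4, Dgat2 and Alpi were lost in 5 of the 6 fits without 1 array each (adjusted p up to 0.0874, 0.213 and 0.194), each of them without wild type replicate 1, 2 or 3 or ISR2 replicate 1 or 3. Treh was lost without wild type replicate 1 or ISR2 replicate 1 (up to 0.0582), and Hsd17b6 without wild type replicate 1 (0.0533).

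Fatty acid oxidation genes included 2 rises and 1 fall among 15 measured; adjusted over the list alone, 6 rose and 2 fell. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, rose 2.31-fold and Acadl, a mitochondrial acyl-CoA dehydrogenase, rose 2.02-fold (adjusted p = 0.00122 and 0.00397). Angptl4, an inhibitor of lipoprotein lipase, fell by 1.07 on the log2 scale (SE 0.15). Camera gave adjusted p = 0.000722 with the preset correlation and adjusted p = 0.647 with an estimated correlation. The list did not pass fry (adjusted p = 0.2485). Among 10 bile acid genes, Abcc3, a basolateral exporter, rose 1.99-fold and Slc10a2, the apical bile acid transporter, rose by a measured 2.02-fold from a low level not shown to be above background (4.62 to 5.63). Slc51a, a subunit of the basolateral transporter, fell by 0.67 (SE 0.13); its call was lost in 5 of the 6 fits without 1 array, the exception being wild type replicate 2 (adjusted p up to 0.152), and also after median centring. Adjusted over the list alone, 3 bile acid genes rose and 1 fell; the list did not pass camera (adjusted p = 0.605), and its median of -0.22 was opposite in sign to its mean of 0.01 and to the test. That median was -0.26 to -0.10 without 1 array at a time, -0.14 after median centring and -0.06 without wild type replicate 3 and ISR2 replicate 2.

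Markers of T cells and intraepithelial lymphocytes were lower. Of 13 measured, 6 fell and none rose; adjusted over the list alone, 7 fell. Cd7 fell by 1.41 on the log2 scale (SE 0.18), Gzmb, which encodes granzyme B of cytotoxic cells, by 1.43 (SE 0.20), Cd3e, a chain of the T cell receptor complex, by 1.08 (SE 0.17) and Cd8a by 0.91 (SE 0.17). The list's median was -1.03. Camera gave adjusted p = 2.3e-07 with the preset correlation and adjusted p = 0.335 with an estimated correlation. Fry gave adjusted p = 0.0486, downward. The number that fell was 3 without wild type replicate 1, wild type replicate 2 or ISR2 replicate 3 and 4 without ISR2 replicate 1, and 3 with all rows tested; Cd8a was among those lost without the former 3 arrays (adjusted p up to 0.118). The smooth muscle and stroma list, measured beside it, varied by an SD of 1.02 between wild type arrays.

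Genes of MHC class II and epithelial defence fell in 6 of 13 measured members, and in 8 adjusted over the list alone. Nos2, the inducible nitric oxide synthase, fell by 1.56 (SE 0.25), H2-Ab1, an MHC class II chain, by 1.43 (SE 0.24), H2-DMa, which loads peptide onto class II, by 1.13 (SE 0.22) and Reg3a, an antimicrobial lectin, by 1.11 (SE 0.21). Camera gave adjusted p = 9.8e-07 with the preset correlation and adjusted p = 0.335 with an estimated correlation, and fry gave adjusted p = 0.0607. Only 2 members fell without wild type replicate 1, wild type replicate 2 or ISR2 replicate 3, and 3 without wild type replicate 3 or ISR2 replicate 1; with all rows tested 1 fell. H2-Ab1 was lost without wild type replicate 1 or 2 (adjusted p up to 0.0701), Reg3a without ISR2 replicate 1 or 3 (up to 0.126), and H2-DMa without any wild type array or ISR2 replicate 3 (up to 0.137). The B and plasma cell and myeloid lists, which hold markers of some other cells that carry class II, were lower in part, without passing. Of the B and plasma cell genes 8 of 9 were lower (median log2 change -0.35, camera adjusted p = 0.161). Of the myeloid genes 10 of 12 were lower (median -0.14, camera adjusted p = 0.676), while Cd14 rose 2.23-fold. Without 1 array at a time these medians were -0.53 to -0.17 and -0.28 to -0.05, and with array weights -0.13 and -0.04; after median centring the myeloid median was -0.06, and without wild type replicate 3 and ISR2 replicate 2 it was 0.01. In ISR2 replicates 1, 2 and 3 the mean of the B and plasma cell list was 6.42, 5.87 and 5.97 and that of the MHC class II list 8.35, 7.70 and 7.75; in the wild type replicates they were 6.26, 6.58 and 6.33 and 8.88, 8.85 and 8.46. H2-Ab1, Cd79a of B cells and Cd68 of macrophages were each lowest in ISR2 replicate 2 (9.14, 4.14 and 6.18). The level of Cd79a there was not shown to be above background. Not every marker followed: Cd79b was lowest in ISR2 replicate 3 (6.43), Ms4a1 in wild type replicate 1 (4.18) and Cd14 in wild type replicate 2 (5.67). Replicate 2 was also the lowest ISR2 array for the means of the Paneth, stem cell and cell cycle lists (9.84, 6.91 and 7.35).

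**Figure D3:**
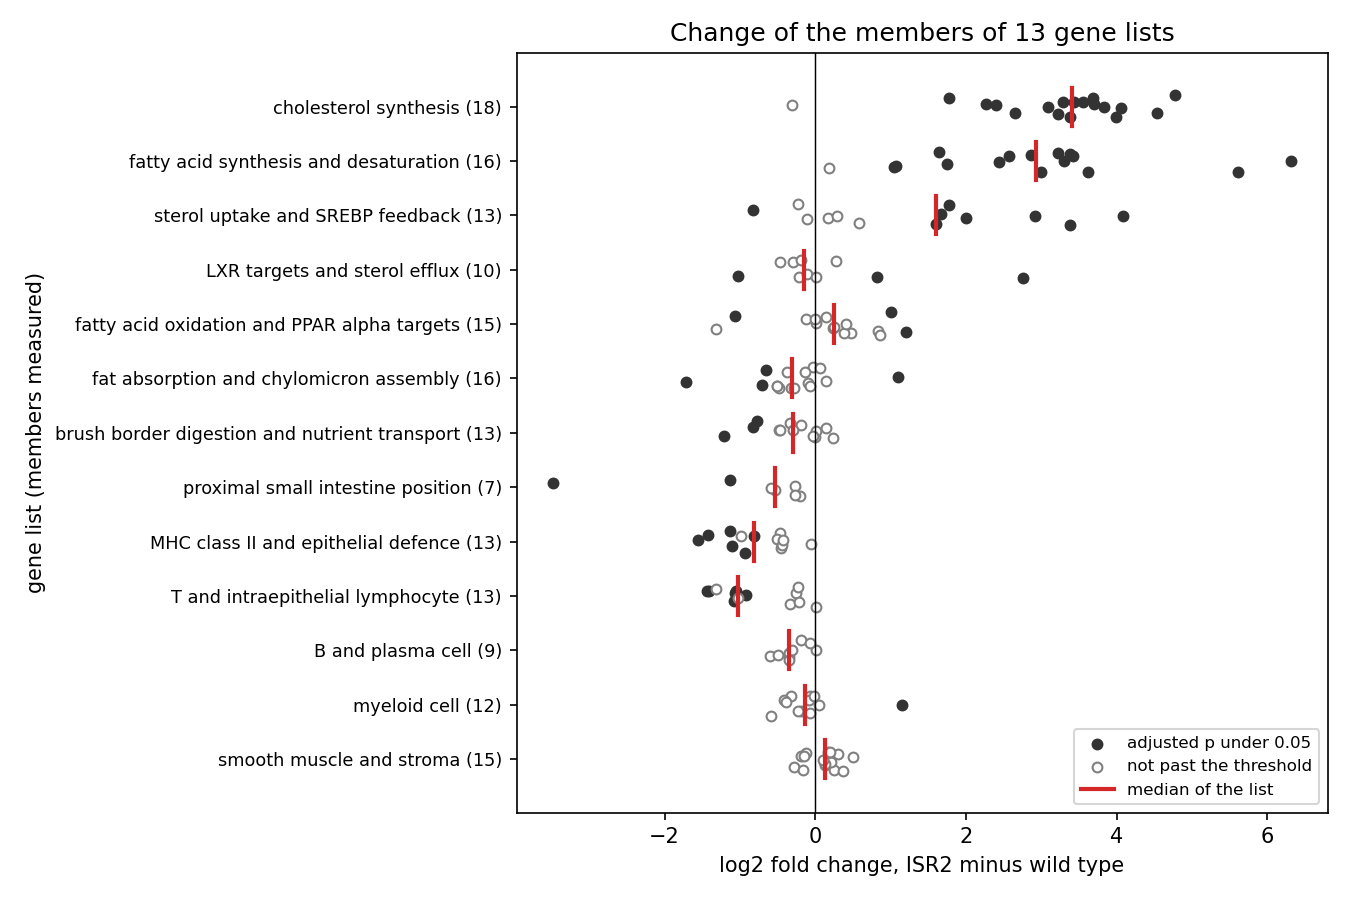
Each point is a measured member of 1 of 13 gene lists, with its log2 fold change (ISR2 minus wild type, 3 arrays each) on the x axis; filled points passed an adjusted p of 0.05, open points did not, and red bars mark list medians. The medians of cholesterol synthesis (3.40) and fatty acid synthesis (2.93) lie far to the right, and those of the T cell (-1.03) and MHC class II (-0.82) lists to the left.

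Markers of other cell types held few calls. No member passed among 11 stem cell, 5 Paneth cell, 14 enteroendocrine, 8 tuft cell, 9 B and plasma cell, 15 smooth muscle and stroma or 9 pancreatic acinar genes measured, and none passed adjusted over the list alone. Their camera adjusted p-values were 0.496, 0.0586, 0.306, 0.262, 0.161, 0.0874 and 0.0884. Several of these lists passed when 1 array was left out. The Paneth list passed downward without wild type replicate 1, ISR2 replicate 1 or ISR2 replicate 3 (adjusted p = 0.00439, 0.0285 and 0.00465), and the B and plasma cell list without wild type replicate 1 or ISR2 replicate 1 (0.0326 and 0.00379). Without wild type replicate 2 the enteroendocrine list passed downward (0.0393) and the stroma list upward (3.1e-06), and without ISR2 replicate 3 the stem cell list passed downward (0.0392). The Paneth list also passed with median centring, quantile normalization or the replicate block (0.0113, 0.033 and 0.0313).

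Lyz1 and Ang4 of Paneth cells stood at -0.67 ± 0.29 and -0.76 ± 0.29 (SE), and Lgr5 of stem cells at -0.29 ± 0.32. Without ISR2 replicate 2 they were at -0.33, -0.43 and 0.11, and without that array and wild type replicate 3 at -0.20, -0.30 and 0.33; Lgr5 was at 0.02 with array weights. Spink4 of goblet cells fell by 0.62 (SE 0.13), a call lost in each of the 6 fits without 1 array (adjusted p up to 0.16) and on median centring, and was the only call among 9, also adjusted over the list alone (camera adjusted p = 0.187). Cd14, a co-receptor for bacterial lipopolysaccharide, rose 2.23-fold and was the only call among 12 myeloid genes, also adjusted over the list alone (camera adjusted p = 0.676). The red blood cell list had 1 measured member, Alas2, at 0.01 ± 0.13, with a sign that changed between fits without 1 array (-0.04 to 0.10).

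The remaining lists gave few calls. Adjusted over the list alone, 1 cell cycle gene rose, 2 interferon genes rose, 1 gene of the unfolded protein response rose and 1 fell, 3 xenobiotic genes rose and 3 fell, and 1 immediate early or heat shock gene rose and 3 fell. Rrm2, which supplies deoxyribonucleotides, rose 1.83-fold and was the only call among 21 cell cycle genes (camera adjusted p = 0.0916); it was lost in 5 of the 6 fits without 1 array, the exception being wild type replicate 3 (adjusted p up to 0.144). The direction of the cell cycle list depended on the array left out. Without wild type replicate 3 or ISR2 replicate 2 it passed camera upward (adjusted p = 3.9e-05 and 0.000105). Without wild type replicate 1 or ISR2 replicate 3 it was downward without passing (adjusted p = 0.929 and 0.869), with medians of -0.17 and -0.20. Rsad2, an antiviral gene, rose 3.62-fold and was the only call among 10 interferon genes (camera adjusted p = 0.12), a call lost without wild type replicate 1 or ISR2 replicate 1 (up to 0.0557), while the list passed upward without wild type replicate 3 (0.00599). Atf4 rose 2.02-fold while Ddit3 fell by 0.85 (SE 0.15) among 13 genes of the unfolded protein response (camera adjusted p = 0.55, upward, with a median of -0.06, or -0.07 to 0.01 without 1 array at a time and 0.06 with array weights, and a mean of 0.03); Ddit3 was lost in 4 such fits, the exceptions being wild type replicate 3 and ISR2 replicate 2 (up to 0.0676). Aldh1a1 rose 1.65-fold, alone among 12 xenobiotic genes (camera adjusted p = 0.883, upward, with a median of -0.15, or -0.27 to 0.09 without 1 array at a time, -0.36 with array weights and -0.07 after median centring, and a mean of -0.16), and was lost in each of the 6 fits (up to 0.14). Fosb and Jun, immediate early genes, fell by 1.41 (SE 0.18) and 1.19 (SE 0.17) among 10 measured (camera adjusted p = 0.292).

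No clock gene passed among 14, and adjusted over the list alone 2 rose and 1 fell. In this list Ciart was 1.82 ± 0.43 (SE; adjusted p = 0.0683) and Per3 was 1.21 ± 0.27 (adjusted p = 0.0504), against 1.11 and 0.80 without wild type replicate 3 and ISR2 replicate 2, where Per3 passed; both passed after median centring, with array weights, with the replicate block and without wild type replicate 2, and Ciart was 6.84, 7.70 and 5.63 in the wild type arrays (camera adjusted p = 0.214 for the list, and 0.00701, upward, without wild type replicate 2). Of 4 measured genes of the Y chromosome and X inactivation, none passed (camera adjusted p = 0.605), also adjusted over the list alone, and Xist was 4.09 ± 0.03 in wild type (mean ± SD, n = 3) with a log2 change of -0.08 ± 0.12 (SE), or -0.01 after median centring. In all, 9 of 28 lists passed camera with the preset correlation, 4 upward and 5 downward. With an estimated correlation 2 passed, and 6 passed fry. Another split of the same 6 arrays, with both genotypes in each group, gave as many as 11 with the preset.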

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

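Signals were also present in rows that the comparison did not use. With all rows fitted together and adjusted over all 35556, 14 of the 1621 rows that list several gene symbols passed an adjusted p of 0.05 in limma, 10 of them higher in ISR2 and 4 lower, with a largest measured rise of 6.20-fold. Of the 14, 5 list Ssty1 or Ssty2, multicopy genes of the Y chromosome. Of the 12146 rows with no symbol here, 52 passed, 41 higher and 11 lower, with a largest measured rise of 10.6-fold. Among rows with 1 symbol, 350 of 21789 passed in the same fit. The share was 0.864% of rows with several symbols, 0.428% of rows with none and 1.61% of rows with 1.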

How the results depend on the processing

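The fit without wild type replicate 3 and ISR2 replicate 2, and array weights in the list test, were chosen only after the results were seen. A total of 157 genes were followed, chosen by the naming rule or after their values were seen. Of these, 91 were called, and none of the 91 changed sign in any setting. In each alternative that tested them 65 passed, and 26 were lost without at least 1 array. Among all 602 calls, more were lost: 272 without ISR2 replicate 1 and 262 without wild type replicate 1, against 110 without ISR2 replicate 2. The cause was not tested for any of the differences here, apart from those made by the number of rows or by the threshold itself.

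With array weights 1268 genes passed (630 rose, 638 fell), where ISR2 replicate 1 had a weight of 4.06 and ISR2 replicate 2 of 0.402. With median centring 155 fell, with all rows tested 106, at an unadjusted p of 0.05 with a 1.5-fold change 404, and at an adjusted p of 0.10 386, against 246. Centring moved the median gene from -0.06 to 0.02. Without 1 array at a time, 335 to 589 genes passed, 236 to 353 rose and 85 to 236 fell. Without wild type replicate 3 and ISR2 replicate 2 together, 775 passed, of which 486 were among the 602. With the intensity trend, the robust option, quantile normalization, the dim filter, the mean of probe sets or a 1.5-fold minimum, 587 to 621 passed. Camera with an estimated correlation called 2 lists against 9; without 1 array at a time 9 to 12 passed, and in all other settings 6 to 10.

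The replicate number as a block gave 778 genes (426 rose, 352 fell) and 10 lists. Deviations of same-numbered arrays correlated at -0.016, 0.323 and 0.540 across genes. Replicates 2 and 3 of both groups correlated best with their own number, and replicate 1 of both groups did not. Deviations from a group mean sum to 0 within the group, so these correlations cannot decide on pairing. The labels do not state that the numbers mark pairs, so the main fit used no block.

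The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 602 genes and was 1 of 10 with as many, and the highest of the others gave 0. For lists it gave 9, 5 of the 10 splits gave as many, and the highest of the others gave 11. Every other split mixes both genotypes in each group, so the genotype difference enters the spread within groups. The counts of 0 genes and 11 lists are therefore not a measure of chance alone. Without background values, no limit of detection was set for dim genes.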

Other observations

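Genes outside the naming rule, chosen after their values were seen, also changed. Acsl4, which activates polyunsaturated fatty acids, rose 11.1-fold (log2 change 3.48 ± 0.12, SE), Aldoc, a glycolytic aldolase, 8.76-fold, Aacs, which activates acetoacetate for lipid synthesis, 8.61-fold and Pank1, which starts coenzyme A synthesis, 7.80-fold. Tecr, of very long chain fatty acid elongation, rose 3.36-fold, Lrp8, an apolipoprotein E receptor, 3.36-fold, Slc25a1, the mitochondrial citrate carrier, 3.18-fold and Mmab, of cobalamin metabolism, 3.08-fold. Klb, the co-receptor of endocrine FGF hormones, rose 4.92-fold, Nfe2l1, a transcription factor anchored in the endoplasmic reticulum, 4.01-fold, and the metallothionein genes Mt1 and Mt2 rose 3.02-fold and 2.68-fold. The adjusted p of Mt2, the largest of these in limma, was 0.00688.

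Genes chosen in the same way that fell included Enpp7, the alkaline sphingomyelinase of the brush border (-2.15 ± 0.31, SE), Slc5a8, a monocarboxylate transporter (-1.99 ± 0.29), Aqp3, a water and glycerol channel (-1.92 ± 0.16) and Rdh9, a retinol dehydrogenase (-1.58 ± 0.20). Lama3 and Lamb3, chains of the same laminin of the basement membrane, were at -1.70 ± 0.17 and -1.20 ± 0.15. Ccl24, a chemokine for eosinophils, was at -1.85 ± 0.16 and Il33, an epithelial alarmin, at -1.15 ± 0.16. Tmprss15, the enteropeptidase that activates trypsinogen, was at -2.28 ± 0.40 and Lrat, which esterifies retinol, at -1.14 ± 0.19. The last pair were lost without wild type replicate 1 (adjusted p up to 0.0904 and 0.0553), and Tmprss15 also without ISR2 replicate 1.

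All tests of the 3 patterns that follow were chosen only after the result was seen. Rows for multicopy genes of the Y long arm were higher in ISR2. The array has 45 rows that list Ssty1 or Ssty2, genes known from the testis, among several symbols. In all 45 the 3 ISR2 arrays lay above the 3 wild type arrays, with a median measured log2 change of 1.53 (1.00 to 1.91), and 5 passed an adjusted p of 0.05 over all rows. Wild type means of the rows ran from 3.06 to 6.20, and no background value shows that the dim ones were detected, so changes from such levels may be lower bounds. The rows share sequence and are not independent. Their means were 4.67, 5.03 and 4.62 in the wild type arrays and 5.87, 6.99 and 5.95 in the ISR2 arrays. A different share of male tissue was argued against: the single-copy Y genes Kdm5d, Eif2s3y and Uty had a median change of 0.026 and at most 0.18 in size. A general rise of dim rows was argued against too, since 16335 other rows in the same wild type range had a median of -0.041. Transgene carriage and a Y chromosome of another origin in the ISR2 mice stay open as untested hypotheses.

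The 10 largest falls had a median log2 change of -2.93. The median gene was at -0.062, so no downward shift of that size was left in the values. Because RMA equalises the arrays, this median could not show a change shared by most genes. ISR2 pieces taken nearer the ileum cannot be told apart from a change at the same place. The proximal list goes with such a shift, with all 7 members lower (median log2 change -0.53, mean -0.92). It passed camera with the preset correlation (adjusted p = 0.000449) and fry (adjusted p = 0.013), but not camera with an estimated correlation (adjusted p = 0.111). This list includes Ada, which is itself among the 10 largest falls. The mean of 7 distal genes, all members of other lists here, moved by -0.207 (SE 0.104), a fall just short of 2 SE. Pieces nearer the ileum would raise this mean, so it does not go with such a shift, unlike the proximal list. Of the 7 distal genes, Slc10a2 was higher, from a low level not shown to be above background (4.62), and the other 6 were lower. A lower share or maturity of enterocytes at the villus tip is a candidate explanation, since 9 tip genes outside the largest falls were all lower, by -0.40 on average (SE 0.08), though none passed alone and 5 of them belong to other lists here. That change is far smaller than the falls themselves. The Paneth, stem cell and cell cycle lists, of cells away from the tip, had medians of -0.55, -0.07 and 0.04, without a matching rise in the main fit. The last 2 medians were 0.27 and 0.59 without wild type replicate 3 and ISR2 replicate 2, and -0.34 and -0.20 without ISR2 replicate 3. A direct effect of the genotype stays open.

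Lower T cell and intraepithelial lymphocyte markers had a list median of -1.03, while the median gene was at -0.062. No shift of the list's size was thus left in the bulk of these values. RMA holds the median gene near 0, so this check could not show a change shared by most genes. The lower markers did not rest on ISR2 replicate 3 alone, since 3 of the 6 members still fell without it. Fewer cells of every non-epithelial type in the scrapings cannot be told apart from a loss of these cells: the stroma list mean minus the T cell list mean rose by 0.89 (SE 0.63), and the stroma list varied widely between wild type arrays. Fewer lymphocytes in ISR2 epithelium, or lower expression in the same number, may both be involved and were not tested.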
